A study of Drosophila melanogaster with 9 samples.

How the data were processed

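Total RNA from heads of newly eclosed male Drosophila melanogaster was measured on 9 Affymetrix Drosophila Genome 2.0 arrays, per the labels. The driver elavII-GAL4, which is active throughout the nervous system, expressed either a 4xUAS control transgene or a transgene for a double-stranded rCAG.rCUG RNA of about 100 repeat units. The double-stranded RNA was studied in 2 independent transgenic lines, S1 and S2. Control, S1 and S2 each had 3 arrays. Per the labels' protocols, flies were kept at 25 °C, RNA was extracted with Trizol and purified on RNeasy columns, and 2 ug of total RNA were labelled with biotin. The labels call the arrays of a group triplicates, and nothing states that they came from separate collections of flies, so the p-values measure the spread between these samples, which may be technical. The number of arrays limits the precision of every value.

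The deposited intensity of each probe set is a MAS5 signal on a linear scale, made with GCOS 1.2 per the submitters' processing notes and named as such in the file headers. The scaling target of that step is not given in the sources used here, and neither is the genome build behind the gene annotation. The authors also deposited detection calls (present, marginal or absent), group means, log2 ratios of the group means and p-values. Per the file headers the p-value columns come from t-tests, which the submitters' design text says were run on raw values among transcripts called present on every array. A check on the deposited table of 18952 probe sets found the authors' group means equal to the mean of the 3 signals within 0.1% for all 18952. The deposited p-values were equal to those of a two-sided test with unequal variances within 0.001 for all 18952. The trimmed mean signal, leaving out 2% at each end, lay between 491.4 and 492.3 on the 9 arrays.

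The 183 Affymetrix control probe sets were left out of the tests, and 18769 remained. Signals were converted to log2 and used without further scaling, because the medians of the 9 arrays differed by 0.372 at most, under the limit of 0.5 set for scaling. A probe set was kept if it was called present on at least 3 of the 9 arrays, which left 13291. Gene symbols were taken from the deposited annotation and matched to current symbols with a table of reference gene names. Of the probe sets kept, 11485 belonged to exactly 1 gene, 1654 to none and 152 to several, and the named ones covered 10411 genes. For a gene with several probe sets (760 genes), the probe set with the highest mean log2 signal stood for the gene. Chromosome arms and positions are those of the deposited annotation. Where a probe set was absent on every array of a group, the fold change is given as a bound. On each of those arrays it takes the lowest signal called present (the floor, between 2.98 and 5.85), or the measured signal where that was higher. Where the measured signals of the whole group lay above the floor, the fitted change is given.

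All 9 arrays were fitted together in limma 3.58.1 (R 4.3.3) with 1 mean per group, 6 residual degrees of freedom and an empirical Bayes step that follows the trend of variance with intensity, with a median of 3.7 prior degrees of freedom. The contrasts were S1 minus control, S2 minus control, the mean of both lines minus control, and S2 minus S1. Unless stated otherwise, the adjusted p-value of a gene or probe set is from limma with Benjamini-Hochberg adjustment over the 13291 probe sets, at a threshold of 0.05. Adjustment over a list alone covers its members, that of a list test covers the lists, that of the share of X-linked genes covers 7 comparisons, and an alternative that changes the filter covers the probe sets it keeps. Errors are standard errors (SE) of limma's log2 change with 3 arrays per group. "Rose", "fell" and "changed" refer to this test. Probe sets changed in both lines were counted when both contrasts passed with the same sign. The count was set beside the overlap of independent lists and beside 100 simulated pairs of unchanged lines that shared the 3 control arrays, since control arrays cannot be split into groups of at least 2.

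The 32 gene lists were fixed from textbook knowledge and the series title. They were Toll signalling, Imd signalling, antimicrobial peptides and humoral effectors, JAK-STAT signalling and Turandot stress peptides, autophagy, lysosome, small RNA and double-stranded RNA binding, RNA-binding proteins linked with repeat RNA or granules, heat shock proteins, endoplasmic reticulum stress, glutathione transferases and antioxidant enzymes, cytochrome P450 enzymes, neuronal and synaptic genes, neuropeptides, glia, photoreceptor, eye pigment, muscle, fat body and lipid metabolism, female-biased yolk genes, haemocytes and melanisation, digestive enzymes, cuticle, ecdysone response, circadian clock, oxidative phosphorylation, cytosolic ribosomal proteins, proteasome, cell death and JNK signalling, insulin and starvation response, glycolysis and trehalose, and odorant-binding proteins. Each list with at least 5 measured members, 31 of the 32, was tested with camera (limma, preset correlation 0.01, two-sided) on 1 probe set per gene, with Benjamini-Hochberg adjustment over the lists. Camera compares a list with the other genes. Fry, which asks whether the genes of a list move one way on balance, and camera with an estimated correlation were run beside it, and with all arrays, or without S2 replicate 3, no camera call held with an estimated correlation. With other arrays left out only the preset correlation was used.

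The rule for named genes was as follows. For each line against control, the 10 genes with the largest rise and the 10 with the largest fall were named among those past the threshold whose arrays lay outside the range of the control arrays. For the mean of both lines, the 12 genes with the largest rise and the 12 with the largest fall in the less changed line were named, and for S2 against S1 the 8 largest in each direction. Each gene list added up to 4 members past the threshold with the lowest p, or up to 2 with the lowest p where none passed. The genes w, Dcr-2, AGO2, r2d2, Tl, spz, cact, dl, Dif, Atg1, Atg8a, ref(2)P, mbl and elav were always given. The comparisons, filters, tests, gene lists, naming rule and most alternatives were chosen before the data were examined.

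The alternatives were quantile normalization, a common median, a filter for presence on all 9 arrays, no filter, an offset of 32 before the log, no intensity trend, 1 probe set per gene, array weights, a replicate block, only the arrays of the groups compared, the methods' t-test with and without adjustment, camera with an estimated correlation, fry, and each array left out in turn. The share of X-linked genes, with and without S2 replicate 3, and the windows along the chromosomes were added after the data had been seen. So were member counts of the gene lists and transposon counts with an array left out, and camera with an estimated correlation without S2 replicate 3. The fit was tested on simulated data for 13291 probe sets with known changes. The noise there was independent between probe sets with the same spread on every array, so the rates below hold only for such data. For S1 against control the fit recovered 20.9%, 58.2% and 83.3% of changes of 0.5, 1 and 2 on the log2 scale, and for S2 against control 20.9%, 61.2% and 84.8%. For the mean of both lines it recovered 29.9%, 68.7% and 87.9%, and for S2 against S1, where nothing had been changed, it called 0. Of the simulated calls, 6.15% (S1), 8.15% (S2) and 5.44% (mean of both lines) were false. In the simulated list test on 10411 genes, with 40 genes per list, 1 of 1 list shifted by 0.5 was called and 0 of 31 unshifted lists were. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.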

Results

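Gene expression was measured in heads of newly eclosed male flies from 3 groups with 3 arrays each. Control flies carried the 4xUAS transgene, and flies of the lines S1 and S2 carried independent insertions of a transgene for double-stranded rCAG.rCUG RNA, all driven in neurons by elavII-GAL4. Between 62.7% and 69.2% of the 18769 probe sets of an array were called present. The median signal was between 68.8 and 74.1 on 8 arrays and 57.2 on S2 replicate 3. That array also stood apart in the log2 ratio of 3' to 5' signal, a sign of RNA quality, which was 3.36 for GAPDH and 4.27 for actin, against 1.14 to 1.71 and 1.76 to 2.77 on the other 8 arrays. The groups differed on this measure too. Every control array (GAPDH 1.39 to 1.71, actin 2.08 to 2.77) had a higher ratio than every S1 array (1.14 to 1.29 and 1.76 to 2.05), a separation that chance gives in 10% of cases with 3 arrays against 3. S2 replicates 1 and 2 also lay below every control array for GAPDH (1.319 and 1.305), but overlapped control for actin (2.133 and 1.986). The SD of the log2 difference between replicates was 0.381 for S2 replicates 1 and 2, 0.743 and 0.746 for the pairs with S2 replicate 3, 0.382 to 0.4 among S1 arrays and 0.434 to 0.618 among control arrays. In limma's array-weight fit, where 1 is average, S2 replicate 3 had a weight of 0.0795 and the others had weights of 0.754 to 2.31.

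**Figure D1:**
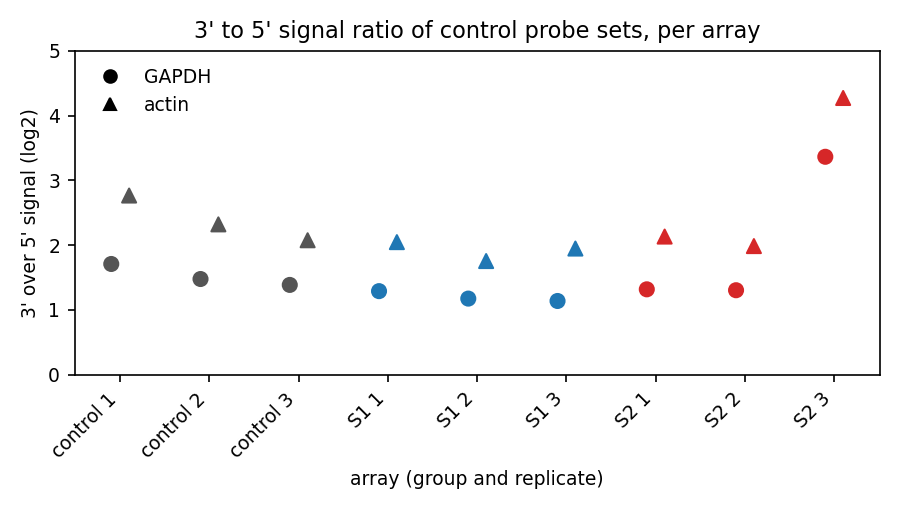
Log2 ratio of 3' to 5' signal (vertical axis) of the GAPDH (circles) and actin (triangles) control probe sets on each array (horizontal axis, by group and replicate), with control in grey, S1 in blue and S2 in red. S2 replicate 3 lies at 3.36 and 4.27, above the other 8 arrays, which reach 1.71 for GAPDH and 2.77 for actin.

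The mean of both lines against control asks which transcripts changed when double-stranded RNA was expressed in neurons, with less weight on either insertion. A gene can pass in this mean when only 1 line differs from control. Among the genes that rose in both lines, NFAT (FBgn0030505, X chromosome), a transcription factor with a Rel-type DNA-binding domain, led with a log2 change of 6.12 (SE 0.455, adjusted p = 5.5e-05). NFAT was called present on 1 of 3 control arrays, and its change ranged from 4.12 to 6.76 over the alternatives in S1. Tsp42Eo (FBgn0033136, 2R), a tetraspanin, rose by 4.00 (SE 0.114, adjusted p = 6.9e-08), and was higher on all 6 line arrays than on any control array. Among the genes that fell, Cyp4p2 (FBgn0033395, 2R), a cytochrome P450, was lower by a log2 change of -3.60 (SE 0.105, adjusted p = 6.9e-08) and Prx6c (FBgn0033518, 2R), a peroxiredoxin, by -3.18 (SE 0.094, adjusted p = 6.9e-08). The gene w (FBgn0003996, X), an eye-pigment transporter used as a marker in fly transgenes, rose by 1.48 (SE 0.168, adjusted p = 0.00099).

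Further genes that rose on all 6 line arrays were CG32440 (log2 change 4.41), CG32437 (3.03), TfIIA-S-2, a small subunit of the transcription factor TFIIA (2.58), Gen, an endonuclease (2.32), CG18577 (2.38), Lsp1alpha, a larval serum protein (1.74), and CG7829 (1.61). CG31308 was absent on every control array and was at least 3.55-fold higher in S1 and at least 2.54-fold higher in S2. CG9522 was absent on every control array as well, at least 2.52-fold and 2.06-fold higher (adjusted p = 0.0184 in the mean of both lines; 0.0547 without control replicate 2, and 0.0508 and 0.0557 without S1 replicates 2 and 3). CG12971, also called absent on every control array but with signals above the floor there, rose by 1.63 in S1 and 1.93 in S2. Genes that fell on all 6 were CG11893 (-3.88), CG12780 (-2.76), CG13813 (-2.52), CtsL2, a cathepsin L-like protease (-2.11), CG14990 (-1.89), Ssl2 (-1.85), CG4017 (-1.84), Cpr72Ec, a cuticle protein (-1.64), and CG31174 (-1.55). Cpr62Ba, another cuticle protein, fell in S2 by 2.89 and in S1, where it was called absent on every array with signals above the floor, by 2.00.

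In this contrast 836 of 13291 probe sets changed, 382 higher and 454 lower, and 214 of them changed by more than 2-fold. They covered 700 genes. At an unadjusted p under 0.05 there were 2673. Without S2 replicate 3, 2595 changed (1371 higher and 1224 lower) and all 836 were among them. For the mean of both lines versus control, changed probe sets numbered 355, 453 and 416 without control replicates 1, 2 and 3, and 524 and 506 without S1 replicates 1 and 2. The members of the 32 gene lists counted as higher and lower, 41 and 63 in all, were 16 and 28, 23 and 30, and 18 and 37 without control replicates 1, 2 and 3. They were 26 and 44 without S1 replicate 1, 24 and 47 without S1 replicate 2, and 116 and 167 without S2 replicate 3.

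The series title names the Toll pathway, an innate immune cascade that ends in the Rel factors dl and Dif. Of 28 measured members of Toll signalling, 2 fell and none rose in the mean of both lines, and 3 fell when adjusted over the list alone. The list was lower than other genes (median log2 change -0.13, camera adjusted p = 0.027; adjusted p = 0.473 with an estimated correlation), with adjusted p = 0.1 without control replicate 1, 0.051 without S1 replicate 2 and 0.094 after quantile normalization. Leaving out S2 replicate 3 gave an adjusted p of 0.0082 (0.574 with an estimated correlation) with 6 members lower, and leaving out any of the control arrays left 0 past limma's threshold. The number lower was 1 without S1 replicate 1 or 2 or S2 replicate 2. The ligand gene spz (FBgn0003495, 3R) fell by 0.41 (SE 0.076, adjusted p = 0.012), and its adjusted p was 0.054, 0.062 and 0.058 without control replicates 1, 2 and 3. GNBP3, a recognition protein gene, fell by 0.26 (adjusted p = 0.0428) and missed the threshold without any of the control or S1 arrays or S2 replicate 2 (adjusted p 0.0562 to 0.148). The log2 change was -0.49 for dl (SE 0.128, adjusted p = 0.054, between 0.005 and 0.193 over the alternatives, and 0.0102 and 0.00495 without S1 replicate 3 and S2 replicate 3), -0.20 for Dif (adjusted p = 0.532), -0.14 for cact (0.499) and -0.01 for Tl, the receptor (0.979). Of 20 members of Imd signalling, the other humoral immune cascade, 1 rose and 1 fell (3 and 4 adjusted over the list alone; median 0.00, camera adjusted p = 0.882). For Imd signalling 3 rose and 6 fell without S2 replicate 3, 1 rose and 2 fell without S1 replicate 3, and 1 rose and 0 fell without any of the control arrays. The member that rose was PGRP-LE, a peptidoglycan receptor, at 0.50 (SE 0.065, adjusted p = 0.002). PGRP-LF, a receptor-like regulator, fell by 0.79 (adjusted p = 0.0169; 0.0699, 0.0595 and 0.0895 without control replicates 1, 2 and 3).

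Among 30 antimicrobial peptides and humoral effectors, 3 rose and 8 fell in the mean of both lines (5 and 11 adjusted over the list alone; median -0.25, camera adjusted p = 0.113). Without S2 replicate 3, where counts of list members were added after the data had been seen, the camera adjusted p was 0.036 (0.85 with an estimated correlation), with 5 higher and 11 lower. Without control replicates 1, 2 and 3 the list had 2 higher each and 1, 4 and 3 lower, and 2 higher and 4 lower without S1 replicate 1 or 2. BaraA2 fell by 1.36 (SE 0.101, adjusted p = 5.5e-05), while the bomanin BomBc1 rose by 1.34 (SE 0.109, adjusted p = 0.0001) and the bomanin BomS4 by 0.38 (SE 0.056, adjusted p = 0.0037). DptB, a diptericin, fell by 1.82 (SE 0.313, adjusted p = 0.0087; 0.055 without control replicate 1). Of 13 members of the JAK-STAT and Turandot list, 3 fell and none rose, also when adjusted over the list alone (median -0.14, camera adjusted p = 0.132). There 1 fell without control replicate 3, and 2 without control replicate 1 or 2. The stress peptide gene TotA fell by 1.51 (SE 0.153, adjusted p = 0.00048). The gene vir-1 fell by 0.56 (adjusted p = 0.012; 0.056 and 0.065 without control replicates 2 and 3). Its S1 arrays (log2 signals 11.482 to 11.961) overlapped control (11.778 to 11.909), and its S2 arrays (10.744 to 11.039) lay below. Socs36E, a feedback inhibitor of the pathway, fell by 0.67 (adjusted p = 0.015; 0.098 and 0.077 without control replicates 1 and 3).

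Autophagy, the other process in the title, showed 0 of 35 genes past limma's adjusted threshold, over all genes or adjusted over the list alone, and 3 at an unadjusted p under 0.05 (median -0.03, camera adjusted p = 0.444). In the fit without S2 replicate 3, 1 rose and 1 fell. Atg1, the initiating kinase, was at -0.03 (SE 0.106, adjusted p = 0.919), Atg8a at -0.06 (adjusted p = 0.779) and Uvrag at -0.23 (adjusted p = 0.158). The gene ref(2)P, the fly p62 cargo receptor, was at -0.32 (SE 0.115, adjusted p = 0.149, between 0.00017 and 0.415 over the alternatives) and passed without S2 replicate 3 at -0.41 (adjusted p = 0.00017). On S2 replicate 3 the autophagy list lay lower than on S2 replicates 1 and 2 (median difference -0.20, percentile 4.05 of random lists). Of 32 lysosomal genes 1 fell, also when adjusted over the list alone (median 0.00, mean -0.01, camera adjusted p = 0.925): Gal, a beta-galactosidase, by 0.51 (SE 0.078, adjusted p = 0.0047). The lysosomal list had 1 higher and 2 lower without S2 replicate 3.

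Of 32 measured genes for small RNA pathways and double-stranded RNA binding 1 fell, also when adjusted over the list alone (median 0.01, camera adjusted p = 0.882). This was vig, which fell by 0.57 (adjusted p = 0.014; 0.079, 0.058 and 0.065 without control replicates 1, 2 and 3). The log2 change was -0.04 for Dcr-2, the siRNA-producing Dicer (SE 0.098, adjusted p = 0.885), 0.03 for AGO2 (SE 0.145, adjusted p = 0.948) and 0.08 for r2d2 (SE 0.063, adjusted p = 0.542). Of 29 RNA-binding proteins linked with repeat RNA or granules, 0 passed in limma, over all genes or adjusted over the list alone, and 3 had an unadjusted p under 0.05 (median -0.02, mean 0.00, camera adjusted p = 0.882). The splicing factor gene mbl, whose product binds CUG repeats, was at -0.17 (SE 0.141, adjusted p = 0.569). Another member, sqd, was at 0.78 (adjusted p = 0.053, and 0.0244 and 0.0169 without control replicate 3 and S2 replicate 3; a second probe set at 0.00). TBPH was at -0.18 (adjusted p = 0.131, and 0.0204 without S2 replicate 3). In the fit without S2 replicate 3, 2 small RNA genes rose and 3 fell, and 2 of the RNA-binding proteins rose and 2 fell. Leaving out control replicate 3 had 1 RNA-binding protein gene pass as higher, and leaving out control replicate 2 had 1 small RNA gene do so.

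In the stress lists, 1 of 21 heat shock genes rose and 1 fell (1 and 1 adjusted over the list alone; median -0.13, camera adjusted p = 0.145). The member that rose was the chaperone gene Hsc70-1, by 0.29 (adjusted p = 0.0358), and it missed the threshold without control replicate 1 or 3, any of the S1 arrays or S2 replicate 1 or 2 (adjusted p 0.0556 to 0.171). Hsp110, which fell by 0.37 (adjusted p = 0.0486), missed it without control replicate 1 or 2, any of the S1 arrays or S2 replicate 1 or 2 (adjusted p 0.0699 to 0.19). Hsp67Bc was at -0.89 (adjusted p = 0.131, between 0.000957 and 0.403 over the alternatives) and Hsp70Bc at -0.62 (0.141, between 5.67e-07 and 0.373), each lowest without S2 replicate 3. With S2 replicate 3 left out the numbers were 1 and 11, with a camera adjusted p of 0.0001 (0.574 with an estimated correlation), and heat shock genes were higher on that array than on S2 replicates 1 and 2 (median difference 0.22, percentile 95.98 of random lists). Of 26 endoplasmic reticulum stress genes 1 rose and 1 fell (1 and 1 adjusted over the list alone; median -0.05, camera adjusted p = 0.38). The member that fell was the chaperone Gp93, by 0.62 (adjusted p = 0.013; 0.083 and 0.054 without control replicates 1 and 2). The one that rose was Thor, a translation repressor gene, by 0.225 (adjusted p = 0.0201; 0.0528 to 0.102 without any of the control arrays or S1 replicate 1 or 2). Of 49 glutathione transferases and antioxidant enzymes, 5 rose and 4 fell (6 and 5 adjusted over the list alone; median 0.02, mean -0.07, camera adjusted p = 0.866). GstD9 rose by 0.41 (SE 0.065, adjusted p = 0.0056), and Prx6c was the named member with the largest fall. GstE14 fell by 0.575 (adjusted p = 0.0093; 0.0512 and 0.0531 without control replicates 2 and 3), and Nmdmc, a mitochondrial folate enzyme gene, rose by 0.41 (adjusted p = 0.0169; 0.0889, 0.0526 and 0.082 without control replicates 1, 2 and 3). Nmdmc lay above control only in S1 (log2 signals 11.189 to 11.501), while S2 (10.469 to 10.672) overlapped control (10.499 to 10.585). Of 74 cytochrome P450 genes, 5 rose and 11 fell (11 and 19 adjusted over the list alone; median -0.06, camera adjusted p = 0.38). Besides Cyp4p2, Cyp4d8 fell by 1.06 (SE 0.1, adjusted p = 0.00031), Cyp6a2 by 0.90 (SE 0.112, adjusted p = 0.0016) and Cyp4ac1 by 0.56 (SE 0.077, adjusted p = 0.0027). Numbers higher and lower in the fit without S2 replicate 3 were 1 and 3 for endoplasmic reticulum stress, 13 and 6 for glutathione transferases and 11 and 24 for cytochrome P450 genes. For endoplasmic reticulum stress they were 0 and 0 without control replicate 1 or 2, and 0 and 1 without control replicate 3 or S1 replicate 1 or 2. Without control replicates 1, 2 and 3 they were 1 and 2, 1 and 1, and 1 and 1 for glutathione transferases and 1 and 4, 1 and 5, and 2 and 7 for cytochrome P450 genes. Without S1 replicates 1 and 2 they were 2 and 2, and 3 and 2, for glutathione transferases, and 3 and 3 without S1 replicate 3 or S2 replicate 2. For cytochrome P450 genes they were 2 and 7 without S1 replicate 1, 2 and 9 without S1 replicate 2 or 3, and 3 and 11 without S2 replicate 2.

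Neuronal genes, whose cells expressed the double-stranded RNA, showed 0 of 49 past limma's adjusted threshold, over all genes or adjusted over the list alone, and 2 at an unadjusted p under 0.05 (median 0.00, camera adjusted p = 0.882). In the fit without S2 replicate 3, 2 neuronal genes passed as higher and 3 as lower, and 1 passed as lower without S2 replicate 1. The neuronal marker elav was at -0.01 (SE 0.053, adjusted p = 0.959). Nlg2, a synaptic adhesion gene, was at -0.30 (adjusted p = 0.057, and 0.0441 and 0.0115 without S2 replicates 1 and 3). Of 34 neuropeptide genes 1 fell over all genes, and 0 in limma adjusted over the list alone, with 6 at an unadjusted p under 0.05 (median -0.03, camera adjusted p = 0.777). This was Mip, which codes for myoinhibitory peptides, at -0.33 (adjusted p = 0.0485), and it missed the threshold without any of the control arrays, S1 replicate 1 or 2, or S2 replicate 1 or 2 (adjusted p 0.0786 to 0.178). Of 19 glial genes 1 fell, also when adjusted over the list alone (median 0.01, camera adjusted p = 0.761): the transporter Indy, by 0.34 (SE 0.049, adjusted p = 0.0036). Of 38 photoreceptor genes 4 rose and 1 fell (5 and 1 adjusted over the list alone; median 0.03, camera adjusted p = 0.113). Among them rdgA, a diacylglycerol kinase, rose by 1.23 (SE 0.118, adjusted p = 0.00034) and the rhodopsin genes Rh3 by 0.36 (SE 0.046, adjusted p = 0.0016) and Rh5 by 0.34 (adjusted p = 0.00944; 0.0567 without control replicate 3). The gene ninaD, a carotenoid uptake receptor, fell by 1.11 (adjusted p = 0.0087; 0.057 without control replicate 1). Photoreceptor genes were higher on S2 replicate 3 than on S2 replicates 1 and 2 (median difference 0.31, percentile 100 of random lists), and without it 7 photoreceptor genes passed as higher and 9 as lower (3 and 0 without control replicate 1). Of 18 eye-pigment genes 1 rose, the marker w, and 1 fell, with the same counts adjusted over the list alone (median -0.13, camera adjusted p = 0.622). The member that fell was bw, a pigment transporter gene, by 0.38 (adjusted p = 0.0364), and it missed the threshold without any of the control arrays, any of the S1 arrays or S2 replicate 1 (adjusted p 0.0536 to 0.167). Another member, rb, a transport gene for pigment granules, was at 0.31 (adjusted p = 0.13, between 0.0154 and 0.382 over the alternatives, and 0.0322 without S2 replicate 3). The fit without S2 replicate 3 had 3 eye-pigment genes higher and 6 lower, 1 and 4 neuropeptide genes, and 1 and 2 glial genes.

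Lists of other tissues moved in part. Of 28 muscle genes 3 rose and none fell (9 and 0 adjusted over the list alone), and the list was higher than other genes (median 0.12, camera adjusted p = 0.001; adjusted p = 0.473 with an estimated correlation, 0.089 after quantile normalization). The troponin C genes TpnC4 and TpnC73F rose by 1.73 (SE 0.2, adjusted p = 0.0011) and 1.17 (SE 0.185, adjusted p = 0.0057). Neither passed in S2 by itself. TpnC4 was at 2.85 in S1 (adjusted p = 0.00012) and 0.61 in S2 (adjusted p = 0.171), and TpnC73F at 1.51 (adjusted p = 0.0038) and 0.82 (adjusted p = 0.055). The actin gene Act88F rose by 1.34 (adjusted p = 0.0116; 0.0684 and 0.066 without control replicates 1 and 3), and Mlc2 was at 0.20 (adjusted p = 0.0501, between 0.0045 and 0.184 over the alternatives, and 0.00516 without S2 replicate 3). Without S2 replicate 3, 12 muscle genes passed as higher and 2 as lower. Of 27 fat body genes 4 rose and 1 fell (6 and 3 adjusted over the list alone; median -0.01, mean 0.09, camera adjusted p = 0.866). Besides Lsp1alpha, Fbp2 rose by 1.06 (adjusted p = 0.0154; 0.0738, 0.0731 and 0.0563 without control replicates 1, 2 and 3), as did Lsp1gamma by 0.58 (adjusted p = 0.0353; 0.0513 to 0.146 without any of the control arrays, S1 replicate 1 or 2, or S2 replicate 2). The lipase gene Lip4 fell by 0.43 (SE 0.069, adjusted p = 0.0062). Of 6 yolk genes 1 rose (1 and 1 lower adjusted over the list alone; median 0.18, camera adjusted p = 0.777), Yp3, by 0.62 (adjusted p = 0.0158; 0.0749, 0.0526 and 0.0832 without control replicates 1, 2 and 3). The Yp3 arrays lay higher in S2 (log2 signals 9.121 to 9.652) than in S1 (8.55 to 8.736), against 8.342 to 8.502 in control. The gene fit of this list was at -1.27 (adjusted p = 0.0563, between 5.87e-05 without S2 replicate 3 and 0.383 over the alternatives). Of 20 haemocyte and melanisation genes 1 rose and 2 fell (2 and 4 adjusted over the list alone; median -0.10, camera adjusted p = 0.38). The serpin genes Spn28Dc and Spn27A fell by 1.32 (SE 0.191, adjusted p = 0.0034) and 0.62 (adjusted p = 0.0248; 0.133, 0.0751 and 0.086 without control replicates 1, 2 and 3, and 0.062 without S1 replicate 1). PPO1, a prophenoloxidase gene, rose by 0.92 (adjusted p = 0.0174; 0.0701 and 0.0547 without control replicates 1 and 2, and 0.0504 without S1 replicate 2), and Sp7 was at -0.22 (adjusted p = 0.0536, and 0.00666 without S2 replicate 3). Among 4 digestive enzyme genes, too few for camera, 1 rose, also when adjusted over the list alone (median 0.18), Mal-A1, a maltase gene, by 0.81 (adjusted p = 0.0113; 0.0531 without control replicate 3). Of 84 cuticle genes 3 rose and 11 fell (3 and 12 adjusted over the list alone; median -0.05, camera adjusted p = 0.373), with Cpr76Bb and TwdlT falling by 0.92 (SE 0.11, adjusted p = 0.0014) and 0.82 (SE 0.106, adjusted p = 0.0018). Of 39 odorant-binding protein genes 3 rose and 6 fell (6 and 10 adjusted over the list alone; median 0.01, camera adjusted p = 0.563). Obp8a fell by 1.49 (SE 0.12, adjusted p = 9.4e-05), Obp57a by 1.11 (SE 0.07, adjusted p = 2e-05), Obp56a by 0.95 and Obp18a by 0.63. Numbers higher and lower in the fit without S2 replicate 3 were 6 and 10 for fat body, 1 and 2 for yolk, 2 and 5 for haemocyte, 6 and 15 for cuticle and 7 and 10 for odorant-binding protein genes. Fat body had 1 and 1 without any of the control arrays and 2 and 1 without S1 replicate 1 or 2 or S2 replicate 2. Haemocyte genes had 0 and 1 without control replicate 1 or 2, 1 and 1 without control replicate 3 or S1 replicate 1, and 0 and 2 without S1 replicate 2. The numbers were for cuticle 0 and 8, 2 and 6, and 1 and 8 without control replicates 1, 2 and 3, 1 and 9 without any of the S1 arrays, and 1 and 10 without S2 replicate 1. For odorant-binding proteins they were 1 and 4 without control replicate 1 and 0 and 6 without control replicate 3.

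Of 20 ecdysone-response genes 1 fell, MsrA, by 0.46 (SE 0.076, adjusted p = 0.0071), and 3 fell when adjusted over the list alone (median 0.01, camera adjusted p = 0.717). The fall of MsrA lay mainly in S2, with log2 signals of 10.192 to 10.354 against 10.892 to 11.123 in control. Its S1 arrays (10.784 to 10.982) overlapped control. ImpL1 and ImpL2 were at -0.43 and -0.38 (adjusted p = 0.0555 and 0.0709, and 0.00244 and 0.0206 without S2 replicate 3). Of 15 clock genes 1 rose, also when adjusted over the list alone (median -0.04, mean 0.06, camera adjusted p = 0.398): the kinase gene sgg, by 0.60 (SE 0.063, adjusted p = 0.0006), whose other probe sets were at -0.25 (adjusted p = 0.083) and -0.17. Of 21 cell death and JNK genes 1 fell, also when adjusted over the list alone (median -0.04, camera adjusted p = 0.373). This was rpr, an activator of cell death, at -0.58 (adjusted p = 0.022; 0.121 and 0.101 without control replicates 1 and 2, and 0.0574 and 0.0605 without S1 replicates 1 and 2). Of 20 insulin and starvation genes 1 rose and 3 fell (2 and 6 adjusted over the list alone; median -0.09, camera adjusted p = 0.373). Besides Thor and Lip4, the receptor genes InR and AkhR fell by 0.49 (adjusted p = 0.0179; 0.0533 to 0.102 without any of the control arrays or S1 replicate 2) and 0.35 (adjusted p = 0.0259; 0.0577 to 0.11 without any of the control arrays or S1 replicate 1 or 3). Thor missed the threshold without any of the control arrays or S1 replicate 1 or 2 (adjusted p 0.0528 to 0.102). Of 19 glycolysis and trehalose genes 1 fell, also when adjusted over the list alone (median 0.01, camera adjusted p = 0.882), Ldh, by 0.61 (SE 0.088, adjusted p = 0.0033). Ribosomal protein genes lay above other genes as a list (median 0.09, camera adjusted p = 1.3e-07; adjusted p = 0.749 with an estimated correlation, 0.15 after quantile normalization), with 2 of 87 that rose (1 adjusted over the list alone). RpS21 rose by 0.34 (SE 0.044, adjusted p = 0.0017) and RpL7A by 0.24 (adjusted p = 0.044; 0.0649 to 0.198 without any of the control arrays, S1 replicate 2 or 3, or S2 replicate 1 or 2). Oxidative phosphorylation genes lay higher too (median 0.08, camera adjusted p = 0.0011; adjusted p = 0.473 with an estimated correlation, 0.238 after quantile normalization), of which 0 of 72 passed in limma, over all genes or adjusted over the list alone, and 10 had an unadjusted p under 0.05. ATPsyndelta was at 0.37 (adjusted p = 0.105, between 1.4e-05 without S2 replicate 3 and 0.332 over the alternatives). Of 31 proteasome genes 0 passed in limma, with 0 at an unadjusted p under 0.05 and 0 adjusted over the list alone (median 0.04, camera adjusted p = 0.373). Prosbeta7 was at 0.125 (adjusted p = 0.306) and Prosbeta1 at 0.10 (adjusted p = 0.399, and 0.0324 without S2 replicate 3). In the fit without S2 replicate 3, 10 ribosomal protein genes were higher, as were 7 oxidative phosphorylation genes (1 lower) and 2 proteasome genes. That fit had 1 ecdysone gene higher and 4 lower, 2 and 4 clock genes, 0 and 3 cell death genes, 3 and 6 insulin genes and 1 and 3 glycolysis genes. Without any of the control arrays 0 insulin and starvation genes rose and 1 fell, and 0 and 2 without S1 replicate 1 or 2. A single ribosomal protein gene was higher without control replicate 1 or 3, S1 replicate 2 or 3, or S2 replicate 1.

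**Figure D2:**
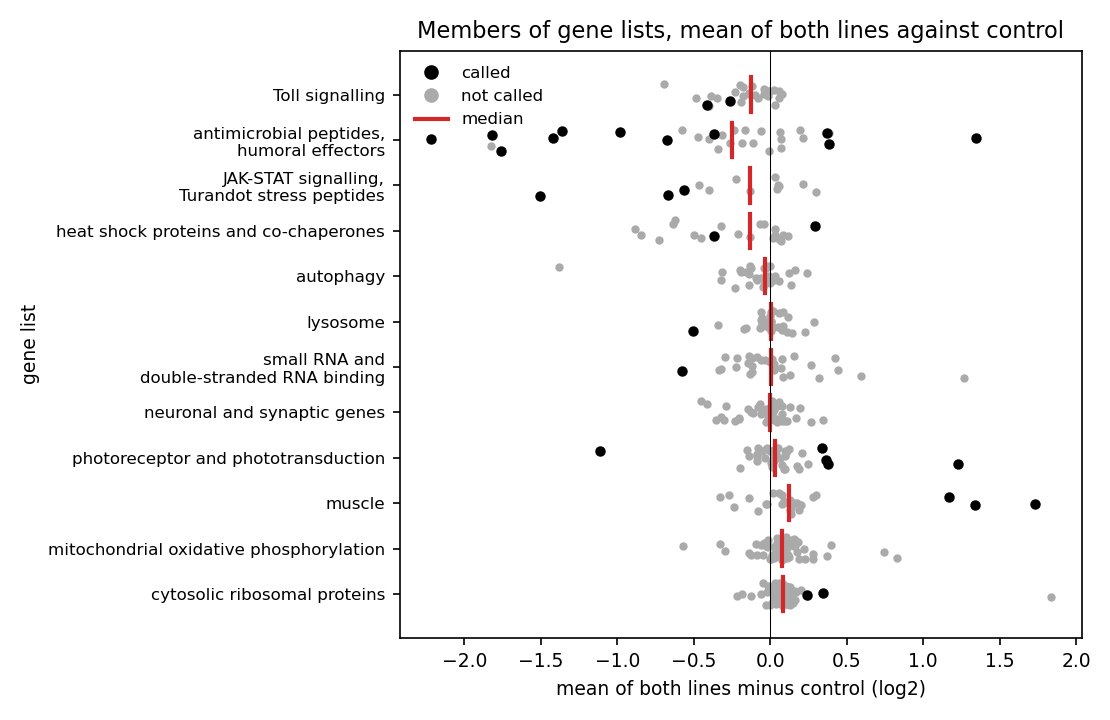
Log2 change of the mean of both lines against control (horizontal axis) of the measured members of 12 gene lists (vertical axis), with genes past the adjusted threshold in black, the others in grey and the list median as a red line. Most genes lie near 0 in every list shown, 0 of 35 autophagy genes and 0 of 49 neuronal genes are black (limma; 3 and 2 at an unadjusted p under 0.05; without S2 replicate 3, 1 higher and 1 lower, and 2 higher and 3 lower), and the antimicrobial list holds 3 black points to the right and 8 to the left.

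The design used independent lines so that changes seen in both could be set apart from changes of 1 insertion. Changes with the same sign passed in both lines for 312 probe sets, 152 higher and 160 lower, and 9 passed with opposite signs. Independent lists of these sizes would share 6.38 higher and 10.1 lower, and simulated unchanged lines against the same controls shared 0.01 on average and 1 at most. The simulated noise was independent between probe sets and had the same spread on every array. It held no shift shared by the genes of an array, and no array as noisy as S2 replicate 3, so it cannot exclude these as sources of shared changes. The correlation of the log2 changes across probe sets, which are not independent replicates, was 0.616 against 0.499 in the simulations, and the covariance was 0.142 against 0.0421, a difference of 0.1. The share with the same sign was 66.3% against 66.6% simulated. The 3 controls could not be split, so both contrasts share them. Leaving out S2 replicate 3 gave 1096 (589 higher and 507 lower), with 311 of the 312 among them. Counted as changed the same way in both lines, probe sets numbered 150, 178 and 164 without control replicates 1, 2 and 3, and 157, 151 and 170 without S1 replicates 1, 2 and 3.

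**Figure D3:**
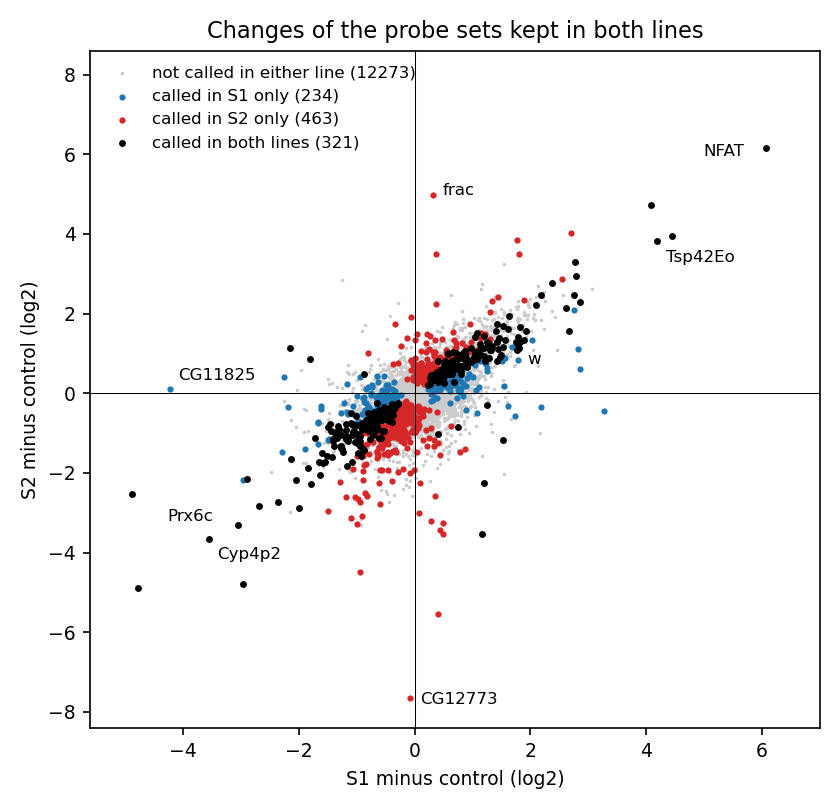
Log2 change of each of the 13291 probe sets kept, in S1 against control (horizontal axis) and in S2 against control (vertical axis), with probe sets past the adjusted threshold in both lines in black (321), in S1 alone in blue (234), in S2 alone in red (463) and in neither in grey (12273). NFAT and Tsp42Eo lie high in both lines, Cyp4p2 and Prx6c low in both, while frac and CG12773 lie far from 0 in S2 alone and CG11825 in S1 alone.

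S1 against control asks what changed in this line. Among genes that changed in both lines, NFAT rose by 6.06 (SE 0.526, adjusted p = 0.00017) and Tsp42Eo by 4.19 (SE 0.131, adjusted p = 3.6e-07), and Cyp4p2 fell by 3.56 (SE 0.121, adjusted p = 3.6e-07). TpnC4 (FBgn0033027, 2R), a troponin C of flight muscle, rose by 2.85 (SE 0.231, adjusted p = 0.00012), and CG30017 by 2.83 (SE 0.403, adjusted p = 0.0039). CG9522 (at least 2.52-fold higher, adjusted p = 0.036) kept its call only without control replicate 1 or S2 replicate 3, with 0.053 to 0.164 when any other array was left out. CG11825 (FBgn0033519, 2R) fell by 4.23 (SE 0.331, adjusted p = 9.9e-05), and the P450 genes Cyp6a9 and Cyp6a19 fell by 2.25 (SE 0.302, adjusted p = 0.0028) and 2.15 (SE 0.155, adjusted p = 8e-05). CG14669 fell by 2.97 (adjusted p = 0.0233; 0.1, 0.0864 and 0.0691 without control replicates 1, 2 and 3, and 0.0622 without S1 replicate 2) and the yolk list gene fit by 2.19 (adjusted p = 0.0131; 0.076 without control replicate 1, and 0.0637 and 0.0631 without S1 replicates 1 and 2). None of the other probe sets of CG14669 passed in S1, at -1.38 (adjusted p = 0.0732), -0.453 (0.579) and 0.939 (0.339). The other genes named by the size of their change in S1 were CG31308, CG32440 (4.08), CG32437 (2.77), CG18577 (2.62), TfIIA-S-2 (2.37), Prx6c (-3.05), CG11893 (-2.96), CG13813 (-2.89) and CG12780 (-2.69), which also changed in S2.

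In S1, 555 probe sets changed, 264 higher and 291 lower (2255 at an unadjusted p under 0.05), and 166 of them by more than 2-fold. Of the 31 lists tested, camera called ribosomal proteins (median 0.09, adjusted p = 4.7e-07; adjusted p = 0.822 with an estimated correlation), muscle (median 0.08, adjusted p = 0.0082; adjusted p = 0.644 with an estimated correlation) and oxidative phosphorylation (median 0.07, adjusted p = 0.0082; adjusted p = 0.644 with an estimated correlation) as higher. RNA quality goes with the group in this contrast, since every control array had a higher 3' to 5' ratio than every S1 array. Without S1 replicate 2 the adjusted p was 0.083 for muscle and 0.129 for oxidative phosphorylation, and for the latter it was 0.094 without control replicate 1. After quantile normalization it was 0.065 for muscle and 0.142 for oxidative phosphorylation. The count without S2 replicate 3 was 2277 (1171 higher and 1106 lower), with all 555 among them. The fit takes its estimate of the spread from every array. For S1 versus control, changed probe sets numbered 252, 298 and 307 without control replicates 1, 2 and 3, and 246, 237 and 257 without S1 replicates 1, 2 and 3.

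S2 against control asks the same of the second line. The extracellular matrix gene frac (FBgn0035798, 3L) rose by 4.97 (SE 0.233, adjusted p = 2.4e-06), and Tektin-C (FBgn0035638, 3L), which codes for a protein of ciliary microtubules, by 3.50 (SE 0.229, adjusted p = 2.8e-05). CG12773 (FBgn0024365, X) and Reepl1 (FBgn0030313, X) were absent on every S2 array and at least 152-fold and 39.3-fold lower than in control. Other falls were those of Kmn1, a kinetochore gene (-3.54, SE 0.219, adjusted p = 2.2e-05), CR14798 (-3.20, SE 0.137, adjusted p = 1.1e-06) and lectin-28C, a C-type lectin (-3.02, SE 0.096, adjusted p = 1.7e-07). Lcp1, a larval cuticle gene absent on every control array, was at least 12-fold higher, and Or65b, an odorant receptor gene, rose by 3.51 (SE 0.486, adjusted p = 0.0028). CG16964, absent on every control and S1 array, was at least 3.04-fold higher than in control (adjusted p = 0.00979; 0.0554 without S2 replicate 1). CG15044 and CG33109 were absent on every S2 array and at least 8.74-fold and 4.64-fold lower (adjusted p = 0.00444 and 0.0382), and CG33109 kept its call only without S1 replicate 2 or S2 replicate 3, with 0.0643 to 0.124 when any other array was left out. The other genes named by the size of their change in S2 were NFAT (6.17), CG32440 (4.74), CG31308, Tsp42Eo (3.82), CG32437 (3.29), CG11893 (-4.80), Cyp4p2 (-3.65) and Prx6c (-3.32), which also changed in S1.

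Of the 30 antimicrobial peptides and humoral effectors, 3 rose and 8 fell in S2 (3 and 14 adjusted over the list alone), and the list was lower than other genes (median -0.30, camera adjusted p = 0.0047; adjusted p = 0.509 with an estimated correlation, 0.058 without S2 replicate 1). The 8 members that fell are all named here, a choice made after their values were seen. CecC, a cecropin, was at -2.95 (adjusted p = 0.0045), the diptericin gene DptB at -2.65 (adjusted p = 0.0026), Mtk, which codes for metchnikowin, at -1.35 (adjusted p = 0.0077) and BaraA2 at -1.32 (adjusted p = 0.00018), and these passed with each array left out in turn. The cecropin gene CecB was at -2.61, and the attacin genes AttA and AttC were at -2.23 and -1.96. Their adjusted p lay between 0.056 and 0.0862 without any of control replicates 1, 2 and 3, and for CecB it was 0.0695 and 0.0688 without S2 replicates 1 and 2. PGRP-SB1 was at -0.36 (adjusted p = 0.047) and passed in no fit with 1 array left out other than that without S2 replicate 3 (0.00044). The median change of the 8 was -2.10, and -2.37 without S2 replicate 3, on which the list was higher than on S2 replicates 1 and 2 (median difference 0.12, percentile 91.16 of random lists). Without that array 4 members passed as higher and 14 as lower, and without any of the control arrays 1 and 4. The numbers were 1 and 7 without S1 replicate 1 or 2, 1 and 8 without S1 replicate 3, and 1 and 6 without S2 replicate 2. In S1, 3 members rose and 2 fell (4 and 4 adjusted over the list alone; median -0.12, camera adjusted p = 0.779), 4 and 6 without S2 replicate 3, and 2 and 1 without any of the control arrays or S1 replicate 1 or 2. On S1 replicates 1 and 2 all 8 genes also lay below every control array, as AttA did at 9.14 and 9.27 against 10.95 to 11.02 in control and CecC at 8.32 and 8.13 against 10.14 to 10.2. S1 replicate 3 was nearer to control, at 10.67 and 9.6.

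**Figure D4:**
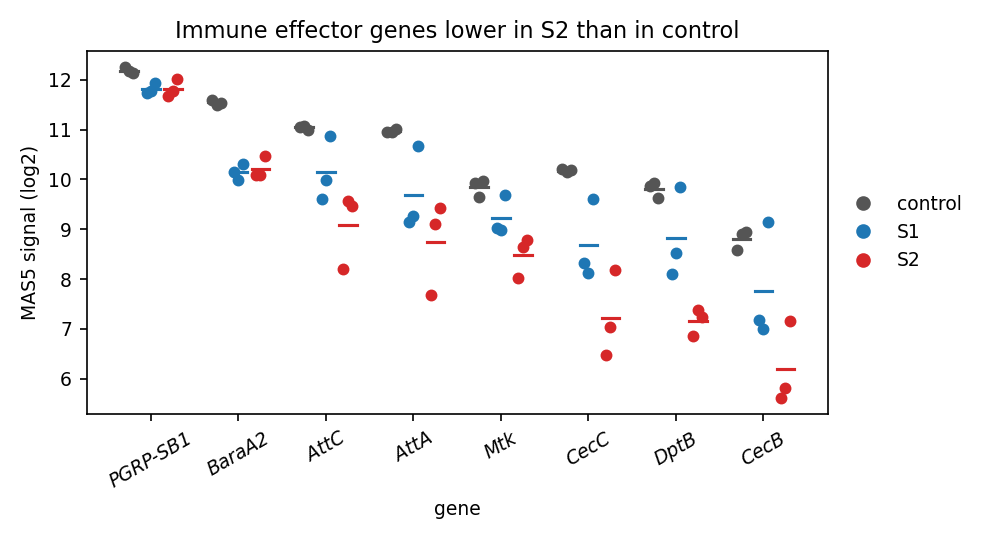
Log2 MAS5 signal (vertical axis) of the 8 immune effector genes that fell in S2 (horizontal axis), with 1 point per array for control (grey), S1 (blue) and S2 (red) and a bar at each group mean. For CecC the control arrays lie between 10.1 and 10.2 and the S2 arrays between 6.47 and 8.18, and for DptB S1 replicate 3 (9.84) lies among the control arrays (9.63 to 9.93).

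Toll signalling was also lower than other genes in S2 (median -0.10, camera adjusted p = 0.034; adjusted p = 0.439 with an estimated correlation), with 3 of 28 members that fell (4 adjusted over the list alone). Its adjusted p was 0.105 without control replicate 1, 0.094 and 0.141 without S2 replicates 1 and 2, 0.102 after quantile normalization and 0.055 among probe sets present on all 9 arrays. Without S2 replicate 3 it was 0.0062 (0.501 with an estimated correlation), with 6 members lower, and 1 member was lower without any of the control arrays, S1 replicate 1 or 2, or S2 replicate 1 or 2. In S2 spz fell by 0.52 (SE 0.088, adjusted p = 0.0082). The heat shock list was lower (median -0.15, camera adjusted p = 0.031; adjusted p = 0.484 with an estimated correlation), with 2 of 21 that fell (1 higher and 6 lower adjusted over the list alone). Its adjusted p was 0.061 without control replicate 1 and 0.122 and 0.145 without S2 replicates 1 and 2, and without S2 replicate 3 it was 6.6e-07 (0.365 with an estimated correlation) with 1 higher and 10 lower. In limma 0 members were lower without any of the control or S1 arrays (1 was higher without control replicate 2), and 1 was lower without S2 replicate 1 or 2.

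Higher than other genes in S2 were ribosomal proteins (median 0.09, camera adjusted p = 4.4e-05; adjusted p = 0.653 with an estimated correlation, 0.805 after quantile normalization at a median of -0.01), muscle (median 0.14, camera adjusted p = 0.0027; adjusted p = 0.439 with an estimated correlation, 0.102 after quantile normalization) and oxidative phosphorylation (median 0.09, camera adjusted p = 0.0047; adjusted p = 0.439 with an estimated correlation, 0.43 after quantile normalization). The same held for the proteasome (median 0.08, camera adjusted p = 0.011; adjusted p = 0.439 with an estimated correlation, 0.327 after quantile normalization). Photoreceptor genes were higher as well (median 0.11, camera adjusted p = 0.011; adjusted p = 0.653 with an estimated correlation, 0.471 after quantile normalization, 0.105 without control replicate 1), with 4 of 38 that rose and 1 that fell (6 and 1 adjusted over the list alone). That call rested on S2 replicate 3, where photoreceptor genes stood higher than on S2 replicates 1 and 2: without it the median was 0.01, the direction in camera turned and the adjusted p was 0.861, with 6 members higher and 4 lower. These numbers were 2 and 0 without control replicate 1 or 2, and 3 and 0 without control replicate 3 or any of the S1 arrays.

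In S2, 784 probe sets changed, 321 higher and 463 lower (2759 at an unadjusted p under 0.05), and 267 of them by more than 2-fold. Leaving out S2 replicate 3 gave 1862 (942 higher and 920 lower), with 779 of the 784 among them. For S2 versus control, changed probe sets numbered 404, 470 and 403 without control replicates 1, 2 and 3. In the authors' deposited table, at an unadjusted p under 0.05 among probe sets present on all 9 arrays, 2416 differed between S1 and control (1195 higher in S1), 1275 between S2 and control (530 higher in S2) and 646 in both with the same sign (258 higher and 388 lower).

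S2 against S1 tests where the lines themselves differed. CG12773 and Reepl1 were absent on every S2 array and at least 143-fold and 52.1-fold lower than in S1. The gene lectin-28C was lower in S2 by a log2 change of -3.10 (adjusted p = 1.4e-07), CR14798 by -3.49 (adjusted p = 1.1e-06) and Kmn1 by -4.04 (adjusted p = 9.4e-06). The DNA photolyase gene phr was lower by -3.46 (adjusted p = 2.1e-06), at 1.21 in S1 and -2.25 in S2 against control. The gene frac was higher in S2 by 4.66 (adjusted p = 4.9e-06), CG11825 by 4.35 (adjusted p = 0.00013), and Tektin-C by 3.14 (adjusted p = 9.5e-05). The P450 genes Cyp6a19 and Cyp6a9 were higher by 3.28 (adjusted p = 3.2e-06) and 2.65 (adjusted p = 0.0017). Cyp6a19 fell in S1 and rose in S2, by 1.13 (adjusted p = 0.0028), and Crg-1 did likewise (-1.81 in S1 and 0.86 in S2).

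Between the lines 221 probe sets differed, 85 higher and 136 lower in S2 (1838 at an unadjusted p under 0.05), 85 of them by more than 2-fold. Leaving out S2 replicate 3 gave 694 (309 higher and 385 lower), with all 221 among them, and it was 98, 114 and 86 without S1 replicates 1, 2 and 3. As a list, antimicrobial peptides and humoral effectors were lower in S2 than in S1 (median -0.19, camera adjusted p = 0.00034; adjusted p = 0.772 with an estimated correlation), with 2 of 30 that differed, both lower (11 adjusted over the list alone, and 10 over all genes without S2 replicate 3). None of the members passed in limma without S2 replicate 1 or any of the control arrays, and 1 did without any of the S1 arrays. So were glutathione transferases and antioxidant enzymes (median -0.18, camera adjusted p = 0.00016; adjusted p = 0.258 with an estimated correlation), with 6 of 49 lower (9 adjusted over the list alone, and 1 higher and 10 lower over all genes without S2 replicate 3). The number lower was 3 without any of the control arrays, S1 replicate 1 or S2 replicate 2, and 2 without S1 replicate 2 or 3. Nmdmc was among them at -0.75 (adjusted p = 0.003). Proteasome genes were higher in S2 (median 0.11, camera adjusted p = 0.0004; adjusted p = 0.258 with an estimated correlation), with 0 of 31 past limma's adjusted threshold, 11 at an unadjusted p under 0.05 and 3 adjusted over the list alone. For this list, leaving out S2 replicate 3 gave a camera adjusted p of 1.1e-05 (0.38 with an estimated correlation) with 4 higher. Female-biased yolk genes were higher too (median 0.68, camera adjusted p = 0.00056; adjusted p = 0.205 with an estimated correlation), with 1 of 6 past the threshold, Yp3, a yolk protein gene, at 0.83 (adjusted p = 0.018), and 4 adjusted over the list alone. Of these 6 genes, 3 passed without S2 replicate 3. The adjusted p of Yp3 was 0.0918, 0.0977 and 0.0707 without S1 replicates 1, 2 and 3 and 0.0586 and 0.0637 without S2 replicates 1 and 2. The same was seen for glycolysis genes (median 0.12, camera adjusted p = 0.02; adjusted p = 0.931 with an estimated correlation), of which 0 of 19 passed in limma, over all genes or adjusted over the list alone, and 1 had an unadjusted p under 0.05. Glycolysis genes stood higher on S2 replicate 3 than on S2 replicates 1 and 2 (median difference 0.27, percentile 99.27 of random lists), and without it the median was 0.04 and the adjusted p 0.533. After quantile normalization the adjusted p of this list was 0.111. Heat shock genes were not called between the lines (median -0.09, camera adjusted p = 0.0528; adjusted p = 0.795 with an estimated correlation), with 0 of 21 past limma's threshold, over all genes or adjusted over the list alone, and 6 at an unadjusted p under 0.05. They stood higher on S2 replicate 3 than on S2 replicates 1 and 2 (median difference 0.22). Without that array the list was lower in S2 than in S1 with the preset correlation (camera adjusted p = 9.5e-10, with 9 members lower) and was not called with an estimated one (adjusted p = 0.156).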

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

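The tests of array-wide scaling, of a mislabelled control or S1 array and of a lower share of fat body, the marker counts above 4-fold and 8-fold, and the list test with an estimated correlation without S2 replicate 3 were chosen after the result was seen.

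The difference between S2 and S1 under the same contrast with control was tested directly with limma, and 221 probe sets passed. Genes higher in S2 than in S1 were frac (log2 difference 4.655), CG11825 (4.349), dpn (4.096), Cyp6a19 (3.28), Tektin-C (3.136), Crg-1 (2.664), Cyp6a9 (2.645), CG8100 (2.072), Yp3 (0.826), sgg (0.403) and PGRP-LE (0.402). The other probe sets of sgg went the opposite way, at -0.376 (adjusted p = 0.0695) and -0.363 (adjusted p = 0.64). Genes lower in S2 were GstD9 (-0.452), Obp18a (-0.515), MsrA (-0.643), Nmdmc (-0.75), vir-1 (-0.81), ImpL1 (-1.653), CG11893 (-1.84), TpnC4 (-2.243), CG14419 (-2.936), lectin-28C (-3.103), phr (-3.461), CR14798 (-3.487), CG5568 (-3.579), Kmn1 (-4.038), Reepl1 (-5.94) and CG12773 (-7.562). Of these dpn was absent on every S1 array and at least 8.38-fold higher in S2. CG5568, Reepl1 and CG12773 were absent on every S2 array and at least 3.76-fold, 52.1-fold and 143-fold lower. Without S1 replicate 3 the adjusted p was 0.0762 for dpn, 0.0938 for CG8100, 0.0707 for Yp3, 0.152 for sgg, 0.154 for PGRP-LE, 0.107 for GstD9, 0.119 for Obp18a and 0.119 for CG5568. These also missed the threshold without S1 replicate 2 (0.0548 to 0.162). All but dpn missed it without S1 replicate 1 (0.0539 to 0.107), all but GstD9 without S2 replicate 1 (0.0503 to 0.104) and all but CG5568 without S2 replicate 2 (0.0616 to 0.103). Without control replicates 1, 2 and 3 it was 0.0597, 0.0694 and 0.0505 for dpn and 0.0538, 0.0686 and 0.0595 for PGRP-LE. For sgg it was 0.0551 without control replicate 1. The other genes named here kept their call with each array left out in turn. Between the lines the camera test called the antimicrobial and humoral effector list (median difference -0.187), glutathione transferases and antioxidant enzymes (-0.175), yolk genes (0.676), the proteasome (0.113) and glycolysis (0.123). With an estimated correlation their adjusted p was 0.772, 0.258, 0.205, 0.258 and 0.931, and that of glycolysis in the test with the preset correlation was 0.533 without S2 replicate 3. The heat shock list was not called between the lines (camera adjusted p = 0.0528; 0.795 with an estimated correlation), and without that array it was lower in S2 with the preset correlation (9.52e-10) and not called with an estimated one (0.156).

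For each line against control, and for S2 against S1, the 6 arrays allow 10 splits into groups of 3, too few for a share under 0.05. In S1 the real split gave 555 probe sets and the highest other split 0. In S2 these were 784 and 0, and between the lines 221 and 0, and 1 split in each gave as many. Of 100 splits of the 9 arrays into 3 groups of 3, 1 gave as many as the real one, itself, both for the mean of both lines (836, with 445 in the highest other) and for changes shared by the lines (312, with 183 in the highest other). These splits cannot exclude chance, because only 1 of the others drawn kept the 3 control arrays together. The rest mixed control and line arrays, so real group differences would widen their spread and lower their counts. Nor can they speak for differences between collections of flies, since the triplicates may be technical.

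The 312 probe sets that changed the same way in both lines, among them those of NFAT, Tsp42Eo, Cyp4p2 and Prx6c, would also arise if the control stock differed from both lines in linked blocks of its genome. Pairs of called genes 100 kb to 2 Mb apart numbered 1157 against a mean of 1096 in random sets on the same arms, at percentile 94.04, just under the 95th percentile of 1160.05 that had been set to exclude linkage. That bound was wrong, since a value so close below it excludes nothing and the genes called in S1 against control lay at percentile 99.69 (92.12 in S2), so linked background and an effect of the RNA cannot be told apart. Sequence variants under the probes of 1 probe set cannot be told apart from a change in transcript level either, because only 6 of the 89 genes changed over 2-fold in both lines had another probe set to compare. Their median ratio to the named probe set was 0.634, with an interval of 0.189 to 0.889 that spans the bound of 0.5, and an effect of the double-stranded RNA itself stays open as the biological explanation.

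S2 replicate 3 stood apart in the probe sets compared, with an SD of 0.743 and 0.746 from the other S2 arrays (0.381 between those) and an array weight of 0.0795. Array-wide intensity scaling is argued against as the cause, since quantile normalization left the weight of this array at 0.0919. Degraded RNA is a candidate explanation, from control probe sets that the comparisons do not use, with 3' to 5' log2 ratios of 3.364 for GAPDH and 4.271 for actin against at most 1.71 and 2.766 on the other 8 arrays. A mislabelled control or S1 array is argued against, since over 65 S2 marker probe sets this array had a median position of 0.794 (95% bootstrap interval 0.696 to 0.909) between the control and S1 arrays (0, with single arrays at -0.0404 to 0.0786) and S2 replicates 1 and 2 (1), with 13 of 14 markers above 4-fold and 6 of 6 above 8-fold on the S2 side. A sample mixed with another genotype, or of a genotype outside the study, cannot be told apart from noise on this array, because 63.1% of the markers (41) lay on the S2 side, between the 50% and 90% set to decide, with 93.2% of 74 in control and 75% of 20 in S1 by the same measure, and no biological explanation was tested.

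Antimicrobial and humoral effector genes were lower in S2 than in control, with a median of -2.098 over the 8 called lower, among them CecC, CecB, DptB, AttA and AttC. The median of these 8 genes kept at least 0.997 of its value without any 1 control array and 1.13 without S2 replicate 3. Their fall did not rest on any of these, but shrank to -1.617 without S2 replicate 1 (-2.311 without S2 replicate 2). They were picked because they passed with all 9 arrays, which favours genes whose control arrays agree. The shares therefore cannot decide for the list whether 1 control array with raised immune genes, or S2 replicate 3, lay behind the pattern. A lower share of fat body would lower its list too. Its median was 0.004 (SE over genes 0.065), or -0.081 (0.097) without S2 replicate 3. There 3 were higher and 9 lower (2 and 0 with all arrays). Bounds of -1.049 and -1.183, 0.5 of the fall of genes picked for falling, cannot decide this. The whole effector list was at -0.304 and -0.367. A biological difference of S2 from control, through line or RNA (not tested), stays a hypothesis found and examined on the same arrays. Whether all 3 control samples shared raised immune expression from their culture stays open, as does whether S1 shares the pattern, since all 8 genes lay below every control array on S1 replicates 1 and 2 but DptB, for example, was at 9.84 on S1 replicate 3 against 8.11 and 8.52.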

How the results depend on the processing

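The counts of gene list members with an array left out were the tests chosen after the result was seen. The counts of changed probe sets stayed within 1.5 times under quantile normalization, a common median, presence on all 9 arrays, no filter, an offset of 32, no intensity trend and 1 probe set per gene. Array weights give S2 replicate 3 a weight of 0.0795. A fit on only the arrays of the groups compared leaves it out for S1, and the mean of both lines has no value there. The methods' t-test pools no spread across genes. In that order, with the t-test first after Benjamini-Hochberg adjustment and then at an unadjusted p under 0.05, for S1 versus control, changed probe sets numbered 2285, 1984, 83 and 2425. For S2 versus control, changed probe sets numbered 2177, 355, 1 and 1285. For S2 versus S1, changed probe sets numbered 1110, 97, 2 and 859. With array weights and by the t-test, adjusted and unadjusted, for the mean of both lines versus control, changed probe sets numbered 2485, 397 and 2156. Counted as changed the same way in both lines, probe sets numbered 1196, 1 and 652. With each array left out in turn the counts were lowest at 237 in S1 (without S1 replicate 2), 403 in S2 (without control replicate 3), 355 in the mean of both lines and 150 in both lines (without control replicate 1) and 86 between the lines (without S1 replicate 3). They were highest, at 2277, 1862, 2595, 1096 and 694, without S2 replicate 3.

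The numbers of the replicates do not pair the arrays: correlations of same-numbered deviations between groups lay between -0.169 and 0.058, and not every sample correlated best with its own number. With a replicate block the counts were 367 (S1) and 205 (both lines), and the others stayed within 1.5 times.

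Of 31 gene lists, 4 were called by camera for the mean of both lines, 0 with an estimated correlation, 0 after quantile normalization, 8 by fry, and with each array left out in turn 3 (without control replicate 1 or S1 replicate 2) to 6 (without S2 replicate 3). The cause of these differences was not tested. The photoreceptor median in S2 was 0.009 without S2 replicate 3, with the camera direction reversed, and 0.171 without S2 replicate 2. Of 163 named values 136 were called, 52 of these in every setting, and 0 called values reversed. Of 27 uncalled, 16 passed in some setting. The methods' t-test after adjustment ended 67 calls. Leaving out control replicates 1, 2 and 3 ended 28, 26 and 26. Array weights or leaving out S2 replicate 3 ended 0 and added 16 each. The other deposited table was not run, as its signals differ by at most 7.21e-06 on the log2 scale. RNA quality was not separated from the group in S1 against control, where the 3' to 5' ratios do not overlap. In the fits without S2 replicate 3 the GAPDH ratio set S2 apart from control as well. S2 replicates 1 and 2 were at 1.319 and 1.305, against 1.387 to 1.71 in control. Their actin ratios (2.133 and 1.986) overlapped those of control (2.076 to 2.766). Low signals limit the fold changes, since probe sets near the signals of 2.98 to 5.85 called present give bounds only.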

Other observations

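The share of X-linked genes, the windows along the chromosomes and the transposon counts with an array left out were tests chosen after the result was seen, as were the elements named here.

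Transposable elements, mobile sequences of the genome, changed more often than other transcripts. Whether this came from the double-stranded RNA or from the genetic background of the stocks was not tested. Of 73 transposon probe sets 20 (27.4%) changed in the mean of both lines, against 816 of the others (6.17%; Fisher's exact test, two-sided p = 1.3e-08 across probe sets, which are not independent replicates). With each array left out in turn the share stayed above that of the others (p between 5.1e-10 and 0.00013, other than 1.6e-15 without control replicate 2). The number was 9 without control replicate 1, 12 without control replicate 3 and 38 without S2 replicate 3. The retrotransposon gypsy fell by 4.78 in S1 and 4.89 in S2 on the log2 scale (mean of both lines -4.83, limma adjusted p = 6.9e-08). Rt1b (-1.03, adjusted p = 0.0051), ZAM (-1.01, adjusted p = 0.0031), HMS-Beagle (-0.81, adjusted p = 0.0031) and blood (-0.75, adjusted p = 0.0047) fell as well. NOF rose by 2.57 (adjusted p = 0.00018), accord by 1.50 (adjusted p = 0.00025) and Tirant by 1.49 (adjusted p = 0.0052). These kept their call with each array left out in turn. In both lines 5 elements rose and 5 fell, and between the lines blastopia was lower in S2 by a log2 difference of -1.41 (adjusted p = 4.2e-05), after a rise of 0.40 in S1 and a change of -1.01 in S2 against control.

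Genes that differed between S2 and S1 lay on the X chromosome more often than elsewhere. Of 1677 X-linked genes 53 (3.16%) differed, and of 8617 autosomal genes 133 (1.54%). These genes are not independent replicates. The odds ratio was 2.08 (95% interval 1.48 to 2.9, Fisher's exact test, two-sided p = 2.2e-05, adjusted over 7 comparisons 7.6e-05). Without S2 replicate 3 it was 2.06 (1.69 to 2.5). For S1 against control it was 0.553 (0.397 to 0.755), and for S2 against control 1.04 (p = 0.699 by the same exact test). A 1 Mb window of the X from position 2000001 held 10 called genes of 90, against 6.59 in the fullest window of random sets on average (permutation p = 0.0117 over 10000 draws), among them CG14419, boi and CG2924. The marker gene w, itself not among the called genes, lies in this window from position 2684631. An autosomal window, on 2R from position 3000001, held 9 of 130 (permutation p = 0.047), so the crowding was not particular to the X. Pairs of genes called between the lines, 100 kb to 2 Mb apart, numbered 704. Random sets on the same arms averaged 612.6 (percentile 99.85). In S2 against control the X window held 15 of 90 (permutation p = 0.329). Whether S2 carries a different X chromosome cannot be told apart from other sources of the difference, because the odds ratio between the lines is the observation itself and that of S2 against control, 1.04 (0.835 to 1.3), neither shows an excess nor excludes a small one.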
